A study of Mus musculus with 4 samples.

How the data were processed

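RNA from sorted LSK bone marrow cells of 4 mice was analysed, 2 WT and 2 Ncstn KO, each group with 1 female and 1 male. Per the labels' protocols, the mice received polyIC at 20 µg per g of body weight 3 times from 14 days of age, and 5 ng of total RNA per sample was amplified and biotin-labelled with NuGEN Ovation reagents before hybridization to Affymetrix arrays. Amplification from so little RNA can favour the 3' end of transcripts and add noise for rare ones. The sexes differ within each group, so the replicates came from separate mice, and apart from the word littermates nothing in the labels ties samples of the 2 groups together.

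The deposited values are probe set intensities on a linear scale, summarised by RMA per the submitters' processing notes; the software, its version and its background model are not given in the sources used here. The scale was settled from the values, which ran from 3.32 to 23642.6, and log2 was taken before any test, although the plan had assumed log2 values. No values from single probes were used, so signal over background was not assessed and differences between dim probe sets carry an unknown error. The arrays had similar but not identical distributions, with median intensities of 71.6 to 79.2, and no scaling was added in the main analysis. A scaling of this kind assumes that most genes do not differ between groups.

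Of 45101 probe sets, 64 control probe sets were left out of the tests. Gene symbols came from the platform annotation of GEO dated 2016, in which 34945 of the remaining probe sets named 1 gene, 932 named several and 9160 were unnamed here. Entrez identifiers of 34741 of the first kind matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and no coordinates are given because the build behind the probe sets is not given in the sources used here. Each gene was represented by the probe set with the highest mean over the 4 arrays, which left 18193 genes, of which 9010 had more than 1 probe set. Genes of near-identical sequence, such as the globins, can share probe sets, and those naming several genes were kept out of the gene tests.

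Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, Benjamini-Hochberg adjustment at 0.05), with genotype as the only term for Ncstn KO against WT and with genotype and sex for females against males. With 2 residual degrees of freedom, the fit borrowed a mean of 4.11 prior degrees of freedom from the other genes. Genes changed at least 2-fold with separate arrays were counted without a test. Of the 20 gene lists, 19 were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated and with fry; the sex-linked list served to check the labels. Camera at the preset value takes its precision from the number of genes. It makes no allowance for variation between mice that list members share beyond a correlation of 0.01, so its small p-values do not measure the spread between mice. Members of each list were also adjusted over the list alone, and each list's median was placed among 10000 random lists matched on mean level. The design, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined, except for the scaling to hybridization controls and the crossed pairing. Figures were drawn with matplotlib 3.10.9.

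The named genes were Ncstn, 10 higher and 10 lower genes, up to 4 members of each list with the smallest unadjusted p, and genes of Notch signalling and blood lineages fixed by name. Because no gene passed, the 20 places went to the smallest unadjusted p among genes with a log2 change of at least 1 and a mean above the median of all genes, 8.04. Plet1os, Mx1, Ifih1, Irf9, Cd14 and Mmp8 fell outside that rule and were named after their values were seen. For sex, up to 5 genes per direction past the threshold were named, with Xist added from the sex-linked list. Some members of the lists are not reported here, and counts are over the members measured. Some genes stood in 2 lists, among them Notch1, Notch3 and Gata2.

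The scripts were tested on simulated data with 200 of 18193 genes changed, 20 times for Ncstn KO against WT. When each gene kept its shrunken variance, 61.8% of genes changed by log2 1 and 98.3% of those changed by log2 2 were recovered, with 9.68% of calls false, above the nominal rate. A second simulation, added after that result, drew variances from the fitted prior, as the model assumes, and recovered 23.8% and 80.0% with 4.47% of calls false. These rates hold for the simulated variances, and the first shows that the error rate can exceed its target when they depart from the model. For the lists, simulated with independent genes, camera called 3 of 380 unchanged lists with shrunken variances and 0 of 380 with variances from the prior, and it called a list shifted by 0.5 in 20 of 20 simulations each time. Independent genes leave out the correlation that the estimated version of camera allows for. Alternatives tried were leaving out dim genes, no variance trend, robust shrinkage, sex as a covariate, the replicate number as a block, the mean of a gene's probe sets, every probe set on its own, repeated quantile normalization, centring on array medians, scaling to the hybridization controls and leaving out each array in turn.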

Results

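Gene expression was measured on Affymetrix arrays in lineage-negative, cKit-positive, Sca1-positive (LSK) cells sorted from mouse bone marrow, a fraction that holds hematopoietic stem cells and multipotent progenitors. The study compared WT mice, which carried floxed Ncstn alleles without cre, with Ncstn KO littermates, which carried the same alleles and the Mx1-cre transgene, a recombinase gene switched on by interferon. Ncstn encodes nicastrin, a subunit of the gamma-secretase complex that cleaves Notch receptors. All mice received polyIC, an inducer of interferon, and their LSK cells were taken 4 weeks later at 6 weeks of age. Each group held 2 arrays, 1 from a female and 1 from a male, so that sex was balanced over genotype. The median intensity over 45101 probe sets was 76.7 and 75.0 on WT replicates 1 and 2 and 71.6 and 79.2 on Ncstn KO replicates 1 and 2. Across 18193 genes, which are not independent replicates, Pearson's r between arrays ran from 0.989 between the Ncstn KO replicates, below every pair of a WT with an Ncstn KO array (0.990 to 0.992), to 0.995 between the WT replicates. The number of arrays limits the precision of every value below, and changes are given as log2 Ncstn KO minus WT with the standard error (SE) of the limma fit and n = 2 per group.

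The first comparison asked whether the targeted gene and its pathway differed between the genotypes. Ncstn was lower on both Ncstn KO arrays, at a mean log2 intensity of 7.74 ± 0.23 (SD, n = 2) against 9.02 ± 0.05 (SD, n = 2) in WT, a change of -1.27 (SE 0.22) or 2.42-fold. It fell when adjusted over the list alone, among 5 measured gamma-secretase subunits (adjusted p = 0.00522), but did not pass over all 18193 genes (limma adjusted p = 0.257). A second, dimmer Ncstn probe set had a change of -0.32 (-0.80 as the mean of both), with Ncstn KO replicate 2 at 7.09, above both WT arrays at 6.81 and 6.79. Where the probe sets lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal gives no measure of the share of deleted alleles. The list as a whole did not pass (camera adjusted p = 0.504, median -0.0068). The other subunits did not pass either. Their changes were 0.41 (SE 0.18) for Psen2, 0.08 (SE 0.26) for Aph1b and -0.02 (SE 0.15) for Aph1a. The 3 Aph1a probe sets disagreed, the 2 others giving 0.51 and 0.61, and the sign of Aph1b turned when the arrays were scaled to the hybridization controls.

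Notch targets showed no common direction. Of 13 measured Notch target genes 0 passed, either adjusted over the list alone or over all genes, with 7 above and 6 below WT. Hes1, a transcriptional repressor induced by Notch, had a change of -0.61 (SE 0.30, and -0.34 without WT replicate 2), while Dtx1 had -0.33 (SE 0.21), Nrarp -0.13 (SE 0.15) and Ptcra -0.50 (SE 0.25). Notch3 had a change of 0.98 (SE 0.27) and Il2ra of 0.88 (SE 0.29). A second Nrarp probe set changed by -0.60, with both Ncstn KO arrays below both WT arrays. Ptcra, Il2ra and Dtx1 were dim, at WT means of 3.62, 4.35 and 4.74 against a median of 8.04 over all genes. Such dim members limit what the list can say about Notch output. The list's median was 0.0049 and its mean 0.039, whereas camera, a test of the list against the other genes, gave a downward direction with an adjusted p of 0.843. Among 23 measured Notch receptors, ligands and pathway components 0 passed by either adjustment (camera adjusted p = 0.506), with changes of -0.15 (SE 0.09) for Notch1, 0.02 (SE 0.07) for Notch2, 0.86 (SE 0.28) for Notch4, -0.70 (SE 0.24) for Jag1 and -0.37 (SE 0.14) for Lfng. The median of the Notch target list and the sign of Notch2 turned negative when the arrays were scaled to the hybridization controls.

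Across all genes no gene passed, and those with the smallest p included Selp, Ms4a3 and Elane among the higher and Rtp4 and Emcn among the lower genes in Ncstn KO. Selp, the platelet and endothelial adhesion receptor P-selectin, was 3.81-fold higher (log2 1.93, SE 0.13), and Ms4a3, expressed by granulocyte-macrophage progenitors, was 2.54-fold higher (log2 1.35, SE 0.10), each with a limma adjusted p of 0.0624. Elane, which encodes neutrophil elastase, was 2.28-fold higher (adjusted p = 0.117). The remaining genes named as higher, none of which passed, were Gda (1.76), Fbp1 (1.38), Lgals3 (1.55), Mcpt8 (1.03), AB124611 (1.44), Socs3 (1.20) and Ecm1 (1.47) on the log2 scale. The genes named as lower, which also did not pass, were Rtp4 (-1.33), Emcn (-1.40), Abca1 (-1.51), Mmrn1 (-1.54), Igf2r (-1.46), Ddx4 (-2.14), Nr4a2 (-1.24), Fam241b (-1.22) and Rftn2 (-1.13), beside Ncstn itself. Emcn and Mmrn1 encode an endothelial sialomucin and a platelet and endothelial adhesion protein.

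The limma fit called 0 of 18193 genes at an adjusted p under 0.05, and 1237 genes had an unadjusted p under 0.05 (902 higher and 335 lower), where chance alone gives 909.65. A change of at least 2-fold with both Ncstn KO arrays on one side of both WT arrays was found for 311 genes, 217 higher and 94 lower. The same count was 184 for the split by sex and 79 for the split by replicate number, while an unadjusted p under 0.05 was found for 1254 and 303 genes in fits with that split as the only term. Chance places the arrays of a group on one side for 33.3% of genes whatever the size of the change, and the observed shares were 34.0% for genotype, 40.5% for sex and 24.3% for replicate number. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p under 0.333. Without Ncstn KO replicate 1 the fit called 23 genes and without Ncstn KO replicate 2 it called 27. The 2-fold count then became 566 and 545. Leaving out 1 array leaves 1 genotype with a single sex, so these values and those of the lists below also hold any difference between the sexes. Other scalings of the arrays gave 3 genes after a repeated quantile normalization, namely Selp, Plet1os and Ms4a3, and 62 genes after centring each array on its median. The bacterial and phage hybridization controls were brighter in Ncstn KO by a mean of 0.195 (log2), and scaling to them moved the median change of all genes to -0.17 and the 2-fold genes to 111 higher and 168 lower.

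Granulocyte-macrophage progenitor genes were higher in Ncstn KO as a group. Of 22 measured members 12 rose when adjusted over the list alone and 0 over all genes, and 20 lay above WT, with a median change of 0.45 (camera adjusted p = 1.39e-11, and adjusted p = 0.17 with an estimated correlation). The members that rose included the granule protease genes Elane (1.19, SE 0.11), Prtn3 (0.75, SE 0.10) and Ctsg (0.58, SE 0.08), the transcription factor genes Cebpa (0.34, SE 0.08) and Irf8 (0.43, SE 0.15, and 0.27 without WT replicate 1), and Csf1r, the macrophage colony-stimulating factor receptor gene (0.75, SE 0.16). Spi1 had a change of 0.26 (SE 0.15) and Mpo of 0.01 (SE 0.05), and neither passed; the sign of Mpo turned under the scaling to the hybridization controls. Mature neutrophil and monocyte genes, markers of cells that the sort should exclude, moved the same way, with 17 of 17 members above WT and 5 that rose when adjusted over the list alone (0 over all genes). These were F13a1 (1.64, SE 0.25), Ccr2 (1.50, SE 0.24), Cxcr2 (1.20, SE 0.25), Hp (1.19, SE 0.19) and Cd14 (1.10, SE 0.25), and the list's median was 0.44 (camera adjusted p = 9.96e-08, and adjusted p = 0.627 with an estimated correlation). Without Ncstn KO replicate 2 the median of this mature list was 0.14 and its camera adjusted p 0.0986. The median was 0.19 without WT replicate 2, 0.72 without WT replicate 1 and 1.05 without Ncstn KO replicate 1. The estimated correlation was 0.43 for the mature and 0.0076 for the progenitor list, against the preset 0.01. The hybridization controls, higher by 0.195, moved in the same direction as both lists. Scaling to them gave medians of 0.25 for the progenitor and 0.24 for the mature list. Camera cannot test this offset. The scaling moves all genes of an array alike, and camera compares a list with the other genes. The 3' to 5' log2 difference was higher in Ncstn KO by 0.14 for the actin control and by 0.051 for the Gapdh control, whose arrays overlapped between the groups (0.71 and 0.65 in WT, 0.69 and 0.77 in Ncstn KO).

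Basophil and mast cell genes rose as a list and had the largest median change of the 19 lists. All 9 measured members lay above WT and 7 rose when adjusted over the list alone (0 over all genes), with a median change of 1.10 (camera adjusted p = 1.98e-12, and adjusted p = 0.17 with an estimated correlation). Examples were the protease genes Mcpt8 (1.03, SE 0.12) and Cpa3 (1.10, SE 0.18) and the IgE receptor genes Ms4a2 (1.54, SE 0.25) and Fcer1a (2.10, SE 0.35). Megakaryocyte-erythroid progenitor genes also rose as a list, with 17 of 18 members above WT and a median of 0.56 (camera adjusted p = 9.03e-07, and adjusted p = 0.219 with an estimated correlation). Among them 2 rose when adjusted over the list alone (0 over all genes), Selp and Itga2b, the platelet integrin gene (1.33, SE 0.25). Rhag had a change of 1.04 (SE 0.33), Gfi1b of 0.66 (SE 0.24) and Gata1 of 0.27 (SE 0.38), and none of these passed. Without Ncstn KO replicate 1 the list's median was 0.31 and the change of Gata1 was -0.31. Of 8 measured mature erythroid genes 0 passed by either adjustment (camera adjusted p = 0.322), with changes of -1.30 (SE 0.36) for Alas2, -1.10 (SE 0.35) for Trim10, -1.05 (SE 0.43) for Slc4a1 and 0.86 (SE 0.26) for Car1. Without 1 array they ran from -1.75 to -0.85 for Alas2, -1.55 to -0.65 for Trim10, -1.54 to -0.55 for Slc4a1 and 0.54 to 1.19 for Car1. The list's median was 0.027 and its mean -0.26, with a downward camera direction. Its members Hba-a1 and Epb42 were dim, at 3.04 to 3.20 and 3.26 to 3.53 over the arrays, so the median is a weak summary. Brighter probe sets shared by Hba-a1 and Hba-a2, kept out of the gene tests, changed by -1.18, -1.32 and -1.24. The other globin probe sets changed by -0.44 to 0.42. The hybridization controls moved with the lists that rose, by 0.195, and scaling to them gave medians of 0.90 for basophil and mast cell genes and 0.36 for megakaryocyte-erythroid progenitor genes.

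Type I interferon response genes fell as a group in Ncstn KO. Of 23 measured members 21 lay below WT and 7 fell when adjusted over the list alone (0 over all genes), with a median change of -0.44 (camera adjusted p = 2.51e-12, and adjusted p = 0.17 with an estimated correlation). The members that fell were Rtp4 (-1.33, SE 0.16), Mx1 (-1.31, SE 0.31), Oas2 (-1.17, SE 0.22), Ifit1 (-0.999, SE 0.23), Oas1a (-0.65, SE 0.14), Ifih1 (-0.57, SE 0.16) and Irf9 (-0.49, SE 0.14), which act in antiviral defence and interferon signalling. Both groups had received polyIC, and only the Ncstn KO group carried the Mx1-cre transgene, so that genotype and transgene cannot be separated here. The hybridization controls moved in the opposite direction, by 0.195, and scaling to them gave a median of -0.64.

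**Figure D1:**
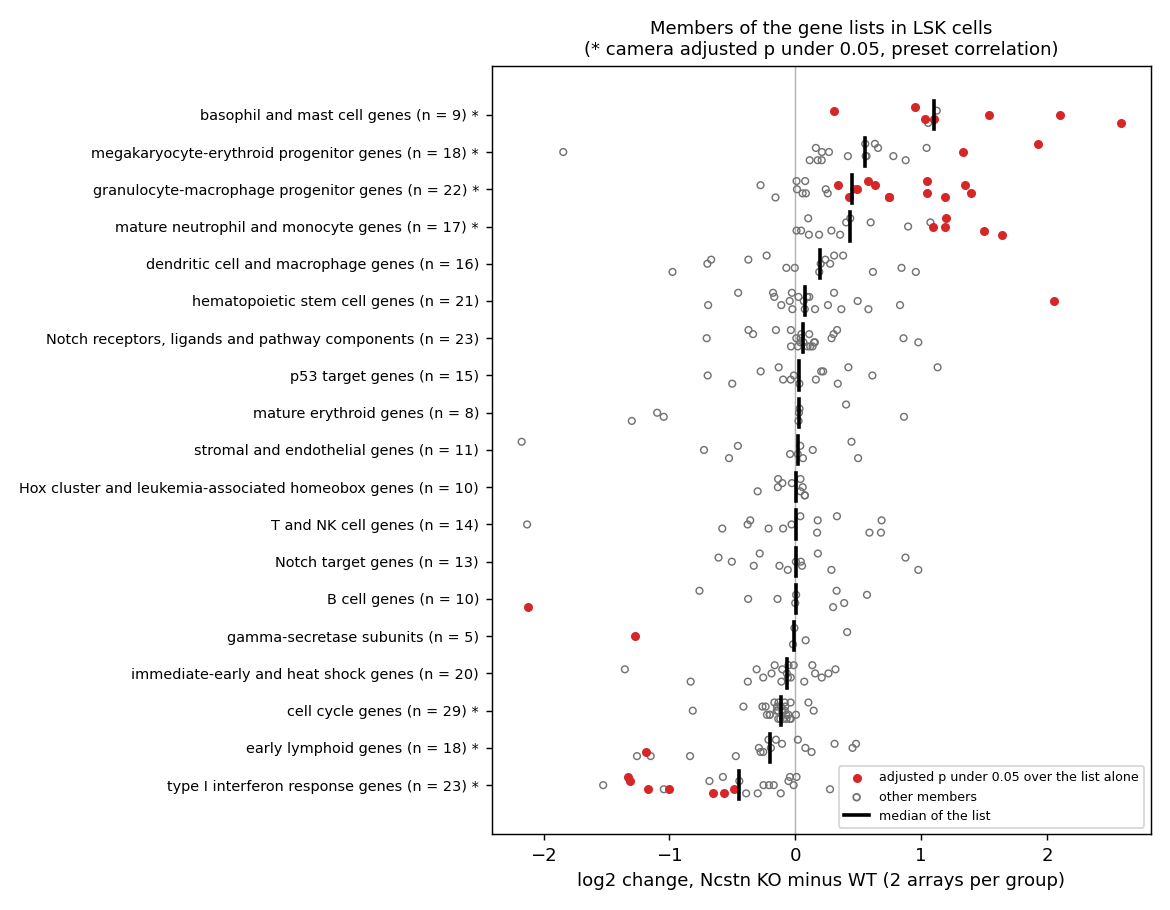
Log2 change (Ncstn KO minus WT, 2 arrays per group) of each measured member of the 19 gene lists, with a black bar at each list's median, filled points for members past an adjusted p of 0.05 over the list alone and a star for lists past camera with the preset correlation. Medians ran from -0.44 for the interferon genes to 1.10 for the basophil and mast cell genes.

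Early lymphoid genes fell as a list by a smaller amount that depended on 1 array. Of 18 measured members 12 lay below WT and 1, the recombinase gene Rag2 (-1.18, SE 0.24), fell when adjusted over the list alone (0 over all genes), with a list median of -0.20 (camera adjusted p = 0.00237, and adjusted p = 0.759 with an estimated correlation). Rag1 had a change of -1.26 (SE 0.40), Blnk of -0.84 (SE 0.36), Dntt of -0.21 (SE 0.09) and Flt3 of 0.13 (SE 0.11), and none of these passed; the sign of Flt3 turned under the scaling to the hybridization controls. Without Ncstn KO replicate 1 the changes were -0.64 for Rag1, -0.34 for Blnk and -0.11 for Dntt. Without Ncstn KO replicate 1 the median was -0.058, the camera direction turned upward and the adjusted p was 0.736, while without Ncstn KO replicate 2 the median was -0.45. Among 10 measured B cell genes 1 fell when adjusted over the list alone (0 over all genes), Ms4a1, which encodes the B cell antigen CD20 (-2.12, SE 0.24). Fcmr (-0.76, SE 0.27), Pax5 (0.39, SE 0.22) and Cd22 (0.30, SE 0.25) did not pass. The B cell list did not pass camera (adjusted p = 0.322), its median being 0.0030 and its mean -0.18, but it passed without Ncstn KO replicate 2 (adjusted p = 0.00174, median -0.24). Cell cycle genes fell as a list by a median of -0.11 (camera adjusted p = 5.38e-05, and adjusted p = 0.759 with an estimated correlation), with 26 of 29 members below WT and 0 past either adjustment. Examples were Tyms (-0.81, SE 0.39), Ccne2 (-0.41, SE 0.25), Mcm5 (-0.17, SE 0.10) and Mcm6 (-0.14, SE 0.09), and without Ncstn KO replicate 2 the list's median was -0.0024 (adjusted p = 0.878) and without Ncstn KO replicate 1 it was -0.27. Scaling to the hybridization controls gave medians of -0.40 for early lymphoid and -0.31 for cell cycle genes. Estimated correlations between members were 0.70 for early lymphoid and 0.81 for cell cycle genes, far above the preset 0.01. The preset p of both lists therefore overstates the evidence.

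The other lists did not pass camera. Of 21 measured hematopoietic stem cell genes 1 rose when adjusted over the list alone (0 over all genes), the sulfotransferase gene Sult1a1 (2.05, SE 0.28), beside changes of 0.31 (SE 0.07) for Gata2, 0.83 (SE 0.28) for Slamf1 and -0.69 (SE 0.19) for Ndn that did not pass in this list. Slamf1 changed by 1.43 in the female and 0.23 in the male pair, and by 0.43 without WT replicate 2. The stem cell list had a median of 0.08 (camera adjusted p = 0.322) and passed without WT replicate 1 (adjusted p = 0.000215, median 0.25) and without Ncstn KO replicate 1 (adjusted p = 0.019, median 0.32). No member passed either adjustment in the lists of T and NK cell genes (14 measured, median 0.0052, mean -0.08, camera direction down, adjusted p = 0.821), dendritic cell and macrophage genes (16 measured, median 0.20, adjusted p = 0.821) or stromal and endothelial genes (11 measured, median 0.020, mean -0.25, camera direction down, adjusted p = 0.394). The same held for p53 target genes (15 measured, median 0.033, adjusted p = 0.9), for immediate-early and heat shock genes (20 measured, median -0.063, adjusted p = 0.166) and for Hox cluster and leukemia-associated homeobox genes (10 measured, median 0.0068, mean -0.041, camera direction down, adjusted p = 0.322). The immediate-early list passed downward without WT replicate 2 (adjusted p = 0.000236, median -0.24) and without Ncstn KO replicate 2 (adjusted p = 1.32e-11, median -0.38) but upward without Ncstn KO replicate 1 (adjusted p = 0.00116, median 0.27). The homeobox list passed downward without Ncstn KO replicate 2 (adjusted p = 0.0488, median -0.25). All of these calls ran in the direction that the sex imbalance left by the missing array gives, since the stem cell (-0.20), immediate-early (-0.46) and homeobox (-0.073) medians were lower in females. Those medians come from the same arrays, so the match cannot tell a sex difference from 1 odd array. With the sexes apart, the median changes in the female and the male pair were 0.13 and 0.11 for stem cell, -0.27 and 0.14 for immediate-early and -0.11 and -0.10 for homeobox genes. Members with the smallest p included Gzma (-2.13, SE 0.70, and -0.99 without Ncstn KO replicate 1) and Thy1 (0.69, SE 0.30) among T and NK cell genes. Those of macrophage genes included Cd68 (0.84, SE 0.24) and Cd5l (-0.98, SE 0.39, dim at a WT mean of 4.24). Among stromal genes they were Sparc (0.50, SE 0.16), Pdgfrb (0.45, SE 0.14), Dcn (-0.53, SE 0.18) and Col3a1 (-0.46, SE 0.17). Dcn and Col3a1 were dim, at WT means of 4.11 and 4.03. Among p53 targets they were Aen (-0.50, SE 0.21), Perp (0.61, SE 0.26), Pmaip1 (1.13, SE 0.49) and Tnfrsf10b (-0.70, SE 0.35). Others were Nr4a1 (-1.35, SE 0.81, and 0.027 without Ncstn KO replicate 1) among immediate-early genes and Hoxa10 (-0.30, SE 0.14) among homeobox genes. Together, camera with a preset correlation called 7 of 19 lists, while camera with an estimated correlation called 0. The directional test of fry, a rotation test of each list on its own, also called 0. Neither of these was tried on simulated lists. With 2 residual degrees of freedom the estimated version can call few lists, so failing it does not show that a list was unchanged. Fry's mixed test, which disregards direction, passed several lists, among them interferon (adjusted p = 0.00175), B cell (0.00381) and stem cell genes (0.0106).

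**Figure D2:**
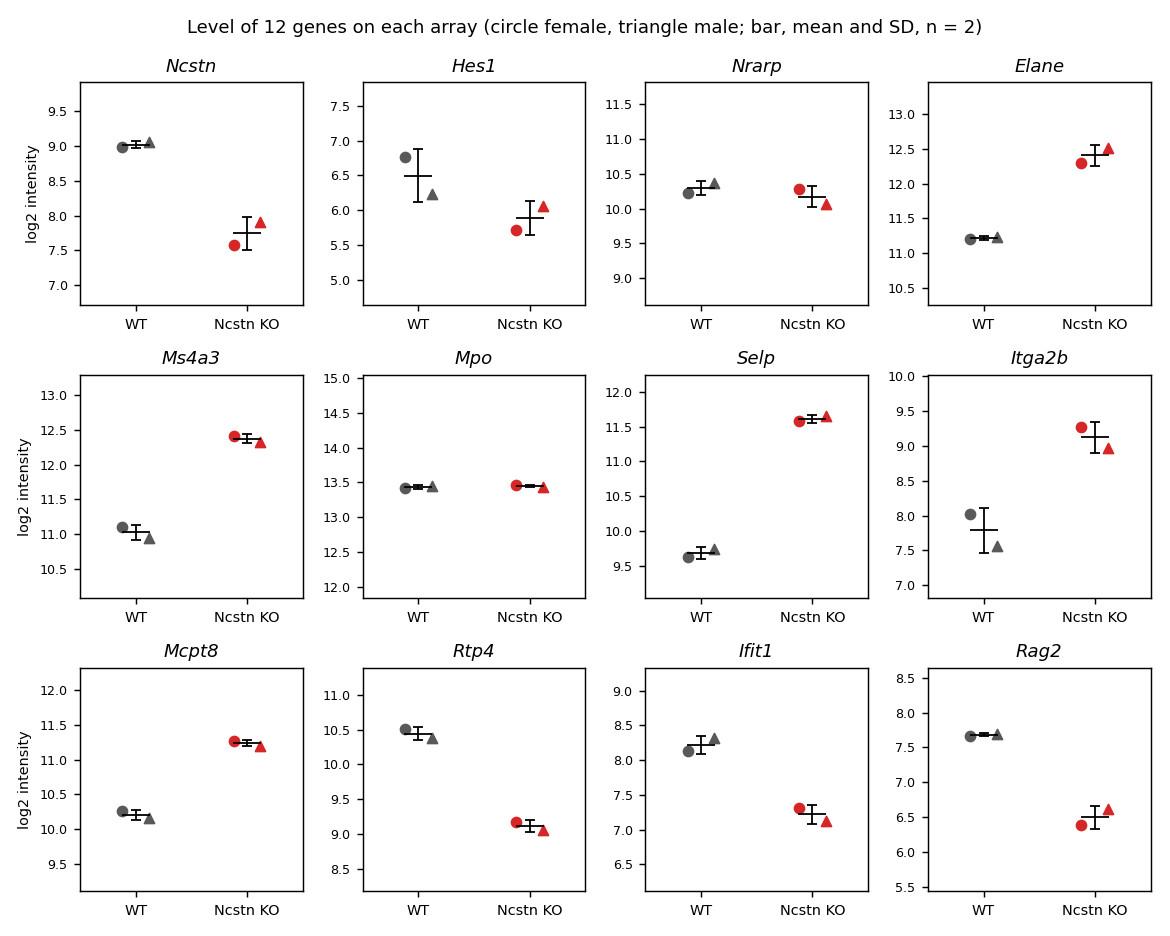
Log2 intensity of 12 genes on each array by genotype, with circles for females, triangles for males and bars for the mean and SD of 2 arrays, each panel spanning 3.2 log2 units. Both Ncstn KO arrays lay below both WT arrays for Ncstn, Rtp4, Ifit1 and Rag2 and above them for Elane, Ms4a3, Selp, Itga2b and Mcpt8, while the mean of Mpo was 13.4 in both groups.

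The comparison of females with males checked the labels of the samples. Expression of the Y-linked genes Eif2s3y, Kdm5d and Uty was lower in both females, with log2 changes (female minus male, 2 arrays each, genotype in the model) of -8.17 (SE 0.29, adjusted p = 0.0244), -6.60 (SE 0.27, adjusted p = 0.0265) and -5.35 (SE 0.21, adjusted p = 0.0265). Xist, the RNA that silences an X chromosome in females, was at 11.9 and 11.8 on the female arrays and at 6.09 and 4.88 on the male arrays, a difference of 6.39 (SE 0.32) that did not pass (adjusted p = 0.0514). The only other call was a probe set annotated to an immunoglobulin kappa variable gene, at 12.2 and 11.7 in the males and 4.76 and 4.73 in the females (-7.18, SE 0.22, adjusted p = 0.0244). Cross-hybridization of that probe set to another transcript, such as a Y-linked one, was not tested. All 4 arrays therefore matched the sex given in their labels. With genotype and sex in the model, the limma fit called 4 genes, all higher in males, and 1561 genes had an unadjusted p under 0.05 (1006 higher and 555 lower in females). It called 0 genes without a variance trend and 58 after centring each array on its median. With dim genes left out it called 2, the kappa probe set and Xist.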

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

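The tests of mature neutrophils and of a single array were chosen after the results were seen, whereas the tests of an intensity-dependent shift were set before. Granulocyte-macrophage progenitor genes had a median change of 0.45 (0.25 with scaling to the hybridization controls) and lay at percentile 100 of 10000 random lists matched on mean level, 95% of which lay between -0.064 and 0.082, which argues against an intensity-dependent shift as the cause. Mature neutrophils in the sorted Ncstn KO cells may contribute: 6 secondary granule and related genes (Camp, Ngp, Ltf, Lcn2, Fcnb and Chil3) changed by a mean of 0.30, 0.22 in the female and 0.37 in the male pair, against 0.92 and 1.01 for Elane, Prtn3, Ctsg and Ms4a3. With sex in the model and 1 residual degree of freedom, the upper 95% bound of the 6 genes was 1.30, above the mean of 0.96 for the 4, whereas the 4 rose by 0.67 more (95% interval 0.24 to 1.10) and all 22 members by 0.19 more (0.056 to 0.33), each with an SE of 0.59 when sex was left out. Mature neutrophils nevertheless stay open, because the 4 genes have the smallest p in the list, the 6 averaged 11.8 in WT, a level that would hide a small share, and the dimmer neutrophil genes Cxcr2 and Mmp8 were higher by 1.20 and 0.90. Loss of Ncstn, or the Mx1-cre transgene that only the Ncstn KO mice carried, stays open and was not tested.

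Type I interferon response genes had a median change of -0.44, and an intensity-dependent shift was tested in the same way. The list lay at percentile 0 of the matched random lists, 95% of which lay between -0.071 and 0.156, which argues against an intensity-dependent shift as the cause. Scaling to the hybridization controls, which moved the median of all genes to -0.17, gave -0.64. A lower interferon response in Ncstn KO may be a difference between the mice, but genotype, transgene and the response to polyIC are confounded and none was tested apart.

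Early lymphoid genes had a median change of -0.20, and that value may rest on 1 array, Ncstn KO replicate 1. Without it the median was -0.058, the camera direction was upward and the adjusted p was 0.736. Rag2 lay below WT on both Ncstn KO arrays, at 6.38 and 6.61 against 7.69 and 7.67. The median change was -0.30 in the female and -0.015 in the male pair. Ncstn KO replicate 1 came from the only Ncstn KO female, so a sex difference within Ncstn KO cannot be told apart from this array. The list's mean level was similar in the WT female (10.24) and the WT male (10.30), against 9.68 on this array. A biological difference between the Ncstn KO mice stays open and was not tested.

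Some changes ran in opposite directions in the female and the male pair, each pair being 1 array against 1, so the difference was not tested. As female change minus male change (log2), the values were 0.45 for Aph1a, 0.52 for Dnajb1, -0.68 for Hoxa5, 0.34 for Nrarp, 0.13 for Notch2, 0.056 for Mpo, 1.54 for Gata1 and -0.35 for Flt3. For list medians they were 0.12 for gamma-secretase subunits, 0.30 for Notch targets, -0.43 for B cell genes, -0.29 for T and NK cell genes, 0.21 for stromal and endothelial genes, 0.28 for cell cycle genes and -0.41 for immediate-early and heat shock genes. Outside the gene tests, the hybridization controls were higher in Ncstn KO by a mean of 0.195, with both Ncstn KO arrays above both WT arrays for 17 of 18 probe sets. Among 10092 probe sets naming no gene or several, 146 changed at least 2-fold with separate arrays, 60 higher and 86 lower in Ncstn KO.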

How the results depend on the processing

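The scaling to the hybridization controls and the crossed pairing were chosen after the data were seen; the other alternatives were planned. The count of genes past the threshold, 0, became 2 with dim genes left out (Selp and Ms4a3; fewer genes tested), 3 with repeated quantile normalization and 62 with arrays centred on their medians, where the prior degrees of freedom were 9.29 in place of 4.11 and the cause was not tested; leaving out 1 array gave 0 to 27, a lone array being assumed to vary like the other group. With the replicate block the count was 0 (smallest adjusted p 0.217), and the block changed no list's call. Deviations of arrays with the same number correlated at -0.24 across genes; the crossed pairing, the same fit as sex as a covariate, also called 0 genes. The 311 genes changed 2-fold became 80 with dim genes left out, 668 with every probe set on its own (378 higher and 290 lower; more features tested) and 419 to 566 without 1 array, while scaling to the hybridization controls gave 279, with 39.8% higher in place of 69.8%. The 7 lists past the threshold became 0 with an estimated correlation and 0 with fry's directional test (smallest adjusted p 0.0768). They numbered 7 or 8 otherwise, although not always the same lists once 1 array was left out. The estimated correlation of the granulocyte-macrophage list was 0.0076, below the preset 0.01, while its unadjusted camera p rose from 2.19e-12 to 0.0189. A larger correlation therefore does not account for the loss of that call. With the correlation estimated, camera uses the 2 residual degrees of freedom, whereas with a preset value it uses the number of genes. Estimated correlations were 0.81 for cell cycle, 0.70 for early lymphoid and 0.43 for mature neutrophil and monocyte genes, so a larger correlation can contribute there. The 4 genes that differed by sex became 2 with dim genes left out (the kappa probe set and Xist, which was not among the 4), 0 without a variance trend and 58 with centring. The count was 5 with robust shrinkage and with every probe set on its own, 6 with the mean over probe sets and with repeated quantile normalization, and 4 without a genotype term. Under the hybridization-control scaling, which moved the median of all genes to -0.17, directions turned for Aph1b (-0.11), Notch2 (-0.17), Mpo (-0.18), Flt3 (-0.066) and the Notch target (-0.19) and T and NK cell (-0.19) lists. The medians alone turned for Notch components (-0.13), stem cell (-0.12), mature erythroid (-0.17), B cell (-0.19), stromal (-0.18), p53 (-0.16) and homeobox genes (-0.19). With dim genes left out, camera's direction turned for the lists of Notch targets (median 0.0049), mature erythroid (0.22), B cell (0.0030), T and NK cell (0.38) and stromal genes (0.47), which then held fewer members. Fry turned the direction for Notch targets (0.0049), and the mean over probe sets turned Aph1a (0.37), Dnajb1 (0.015) and the gamma-secretase (0.18) and stromal (0.040) lists; the cause was not tested. Leaving out 1 array leaves 1 genotype with a single sex, so the ranges that follow also hold any sex difference. It turned the sign of the change or median, or camera's direction, of genes and lists with these ranges: Aph1a -0.20 to 0.16, Aph1b -0.12 to 0.29, Hoxa5 -0.33 to 0.052, Hoxa7 -0.22 to 0.012, Hoxa9 -0.28 to 0.0037, Notch2 -0.039 to 0.080, Mpo -0.0047 to 0.031, Nr4a1 -2.73 to 0.027, Gata1 -0.31 to 0.84, Flt3 -0.0094 to 0.27; and the lists of gamma-secretase -0.12 to 0.16, Notch components 0.039 to 0.12, Notch targets -0.23 to 0.14, stem cell -0.060 to 0.32, mature erythroid -0.11 to 0.044, early lymphoid -0.45 to -0.058, B cell -0.24 to 0.21, T and NK cell 0.0024 to 0.12, dendritic cell and macrophage -0.32 to 0.38, stromal and endothelial -0.16 to 0.087, p53 -0.030 to 0.10, immediate-early -0.38 to 0.27 and homeobox genes -0.25 to 0.057. Further named genes kept their sign but had a log2 change more than 1.5 times smaller in such a fit: Gzma -3.27 to -0.99, Blnk -1.33 to -0.34, Tyms -1.34 to -0.29, Ccne2 -0.76 to -0.066, Mcm5 -0.26 to -0.074, Mcm6 -0.22 to -0.047, Nrarp -0.23 to -0.021, Ptcra -0.80 to -0.21, Pax5 0.16 to 0.61, Perp 0.25 to 0.98, Pmaip1 0.50 to 1.76, Thy1 0.32 to 1.05, Rag1 -1.87 to -0.64, Dntt -0.31 to -0.11, Slamf1 0.43 to 1.23, Slc4a1 -1.54 to -0.55, Trim10 -1.55 to -0.65, Alas2 -1.75 to -0.85, Car1 0.54 to 1.19, Gfi1b 0.37 to 0.95, Rhag 0.69 to 1.40, Hes1 -0.87 to -0.34, Notch1 -0.21 to -0.099, Il2ra 0.51 to 1.24, Hoxa10 -0.43 to -0.17, Irf8 0.27 to 0.59, Cd22 0.17 to 0.43, Fcmr -1.05 to -0.47, Cd68 0.54 to 1.15, Pdgfrb 0.29 to 0.60 and Rftn2 -1.52 to -0.75. The same held for Aen -0.83 to -0.17, Tnfrsf10b -1.09 to -0.30 and Cd5l -1.53 to -0.42. The mean over probe sets moved, by as much, Ncstn (-0.80), Nr4a2 (-0.73), Psen2 (0.18), Aph1b (0.36), Notch4 (0.46), Jag1 (-0.46), Il2ra (0.54), Slc4a1 (-0.66), Cd22 (0.060), Tyms (-0.41), Hoxa10 (-0.051), Dtx1 (-0.20), Nrarp (-0.36), Notch1 (-0.067) and Notch2 (0.0057). It also moved Tnfrsf10b (-0.39), Dcn (-0.26) and Col3a1 (-0.15). The granulocyte-macrophage, basophil and mast cell, megakaryocyte-erythroid and interferon lists kept direction and call without any 1 array. Not run were the sex comparison with a replicate block or with an array left out, where no residual degrees of freedom remain, and robust shrinkage for camera, which has no such option; a covariate cannot move the 2-fold count in this balanced design. Signal over background was not assessed, which limits what can be said of dim genes.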

Other observations

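The values in this part were picked after the data were seen. Of the dendritic cell and macrophage list, 4 MHC class II and invariant chain genes were picked for their values, and none passed over all genes. Female minus male (log2) was 1.78 for H2-Eb1 (adjusted p = 0.574), 1.36 for H2-Aa (adjusted p = 0.352), 1.20 for Cd74 (adjusted p = 0.107) and 0.71 for H2-Ab1 (adjusted p = 0.574). Over the 12 other measured genes of that list the median difference was 0.40, from -0.30 for Vcam1 to 0.96 for C1qc. Ap1s3, a gene of the granulocyte-macrophage list, was at 9.16 on both female arrays and at 6.74 and 6.86 on the male arrays (adjusted p = 0.345). With the correlation estimated, camera for sex had 1 residual degree of freedom, so a list could hardly pass. Of the 19 lists, 7 passed camera for sex with the preset correlation, and each of these had an adjusted p of 0.743 with an estimated correlation. As median female minus male, those lower in females were immediate-early and heat shock genes (-0.46, camera adjusted p = 1.77e-13), mature neutrophil and monocyte genes (-0.36, 1.77e-13), stem cell genes (-0.20, 6.22e-06), early lymphoid genes (-0.17, 6.15e-07) and homeobox genes (-0.073, 0.0459). Those higher were dendritic cell and macrophage genes (0.68, 5.33e-05) and cell cycle genes (0.15, 0.000278). For early lymphoid and cell cycle genes the WT male and female hardly differed. Mean log2 levels of early lymphoid genes were 10.30 in the WT male and 10.24 in the WT female. They were 10.32 in the Ncstn KO male and 9.68 in the Ncstn KO female. For cell cycle genes the levels were 11.37, 11.40, 11.06 and 11.44 in the same order.

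Globin probe sets did not all move alike in Ncstn KO. The 3 shared by Hba-a1 and Hba-a2 changed by -1.18, -1.32 and -1.24 (log2), each with both Ncstn KO arrays below both WT arrays. A probe set naming Hba-a2 alone changed by 0.022. The probe set shared by beta-globin genes changed by 0.42 and those naming Hbb-b2 alone by -0.44 and -0.21. Among probe sets naming no gene or several, 291 were at least 2-fold lower in females with separate arrays and 27 were higher, whereas among the 18193 genes 93 were lower and 91 higher.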
